A study of mouse gut metagenome with 24 samples.

How the data were processed

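Stool DNA of 24 male C57BL/6J mice, 8 weeks old, was amplified over the full length of the 16S rRNA gene and sequenced on a PacBio Sequel IIe. The deposited count table gives reads per amplicon sequence variant (ASV, a distinct 16S sequence inferred from the reads) with whole counts, 1960 ASVs in 24 samples, and a taxonomic name for each ASV. A second table by the authors holds the fraction of each sample's reads in each ASV. It was tested against the count table: every fraction equalled count over sample total to within 9.93e-17, so the counts alone were analysed. No count equals 1 and the smallest count above 0 is 2. The denoising tool, the reference for the names and any filters are not given in the sources used here. How names were assigned is therefore not known here, and a species name is used as the label of a sequence.

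Library totals run from 8787 to 31880 reads, 349534 in all. A count of 0 in a sample still allows a share of up to 3 reads of its total, and intervals for single samples are 95% Wilson intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and such limits cover counting error only. The smallest share that could be seen differed with depth, and richness was therefore compared at 8787 reads.

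Samples were grouped by title into Sham, DSS, DSS with low-intensity pulsed ultrasound (LIPUS) at 0.5 W and DSS with LIPUS at 1.0 W, 6 samples each. Titles and treatment fields conflict for LIPUS power. Samples 1 to 5 of the 0.5 W group carry 0.5 W in the treatment field and sample 6 carries 1.1 W, while samples 1 to 6 of the 1.0 W group carry 1.2, 1.3, 1.4, 1.5, 1.6 and 1.7 W. No sample titled 1.0 W carries 1.0 W in that field, so the power each mouse received is not settled by the labels. Titles number separate mice, so p-values measure the spread between samples. Up to 5 animals shared a cage and the cage of each mouse is not given, so samples of cage mates may not be independent, while every test treats the 6 samples of a group as independent. The groups, lists of taxa, tests, rule for named taxa and most alternatives were fixed before the data were examined.

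Counts were summed by genus and by species name. A genus, species or ASV was tested when it was seen in at least 6 samples with at least 20 reads in all, which left 94 genera, 129 species and 326 ASVs. All groups were fitted together in edgeR 4.0.16 with TMM factors and quasi-likelihood tests, two-sided. Benjamini-Hochberg adjustment was made within each contrast, and a taxon was called at an adjusted p under 0.05. The contrasts were DSS against Sham, each LIPUS group and both together against DSS, the LIPUS groups against each other and each LIPUS group against Sham. Log2 fold changes are relative to the TMM scale, which differs from the scale of percentages because Ligilactobacillus takes a large part of the Sham reads. A fold against a group with 0 reads was computed against 3 reads over that group's pooled libraries. Both the pooled share and the mean share of the other group were set against that limit, and the lower of the 2 folds is given as the bound.

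Phyla and families with a mean of at least 0.1% of reads and 12 fixed lists of taxa were compared as percent of reads by exact permutation of group means, two-sided, with Benjamini-Hochberg adjustment within the contrast. The lists were mucus-associated genera, butyrate producers, facultative anaerobes, lactobacilli and bifidobacteria, Muribaculaceae, the Bacteroides group, Rikenellaceae and Prevotellaceae, Erysipelotrichia, Lachnospiraceae, Oscillospirales, Clostridiaceae with Peptostreptococcaceae, and bacteria foreign to the gut. Sulfate reducers, Helicobacter and segmented filamentous bacteria were also listed, and 0 ASVs carried their names. The list of lactobacilli and bifidobacteria held 2 genera, Lactobacillus and Ligilactobacillus, and that of Rikenellaceae and Prevotellaceae held 1 ASV, named Prevotella. Shannon diversity was the mean of 100 random draws of 8787 reads per sample, and observed ASVs were the number expected at that depth. The Firmicutes to Bacteroidota ratio was taken on the log2 scale with 1 read added to each phylum. Bray-Curtis distances of ASV percentages were tested by PERMANOVA, with all 462 splits of 6 against 6 samples, all 18564 splits of 12 against 6, or 99999 permutations for the 4 groups. The smallest exact p for 6 against 6 samples is 0.0021645.

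Whether LIPUS moved genera back toward Sham was measured as the Pearson correlation across genera of the DSS change with the LIPUS change. The DSS samples were split into separate sets for the pair of contrasts, in all 20 ordered ways. Genera are not independent replicates, so the correlation has no p-value, and simulated groups with no change stand beside it.

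The named taxa follow a rule. For DSS against Sham and LIPUS against DSS they are the 12 called genera of highest mean percent and the 8 with the largest change, the 8 called species of highest mean percent, and every phylum and family that passed. Where fewer than 5 genera were called, the 5 with the smallest p are named with their values. For other contrasts they are up to 5 called genera of highest mean percent. Tested members of a list and the 12 most abundant genera may be named as well.

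Alternatives covered DESeq2 1.42.0, limma 3.58.1 on centred log-ratios with 0.5 added to counts, library totals, other filters, exact permutation of percentages, the number of the sample as a block, other distances, moving the sixth 0.5 W sample to the 1.0 W group, and leaving out each sample in turn. The fit was tested on simulated data with 6 changed genera or species, or 20 changed ASVs, per fold. The changes were seeded at 0.5 W, among the more abundant taxa of DSS, and read from 0.5 W against DSS. Recovery of rarer taxa and the rates for DSS against Sham were not measured. At 4-fold, 16-fold and 64-fold it recovered 30.6%, 85.6% and 98.3% of changed genera, and 9.71% of its calls were false. For species it recovered 15.6%, 64.4% and 95.6%, with 9.92% false calls. For ASVs it recovered 3.5%, 20.0% and 50.5%, with 19.9% false calls. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, and the PERMANOVA was checked against vegan 2.7.1.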

Results

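The series asks whether transcranial ultrasound changes colitis caused by dextran sulfate sodium (DSS), a polymer in drinking water that injures the colon lining of mice. Its stool samples measure the gut bacteria in 4 groups of 6 mice. Sham mice had no treatment, DSS mice received 3% DSS for 7 days, and the other groups received the same DSS and LIPUS for 4 days at 0.5 W or 1.0 W by title, although the treatment fields give 1.2 to 1.7 W for the 1.0 W samples and 1.1 W for 0.5 W sample 6. Library totals ran from 10023 to 19132 reads in Sham (mean 13847), from 11144 to 31880 in DSS (19533), from 8787 to 16712 in the 0.5 W group (12446) and from 10640 to 15863 in the 1.0 W group (12430.3). A count of 0 over the pooled Sham libraries allows a share of up to 0.00361%.

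Ligilactobacillus, a lactic acid bacterium common in mouse stool, made up 55.2% ± 29.5 (SD, n = 6) of reads in Sham. Its level was 11.8% ± 8.01 in DSS, 11.4% ± 14.9 in the 0.5 W group and 10.2% ± 10.9 in the 1.0 W group (SD, n = 6 each). Bacteroides made up 1.24% ± 1.33 of reads in Sham, 8.81% ± 1.83 in DSS, 10.6% ± 3.85 at 0.5 W and 9.61% ± 4.75 at 1.0 W (SD, n = 6 each). Duncaniella, of the family Muribaculaceae, was at 5.61% ± 2.10 in Sham, 5.66% ± 1.44 in DSS, 4.51% ± 2.12 at 0.5 W and 3.96% ± 2.26 at 1.0 W (SD, n = 6 each).

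**Figure D1:**
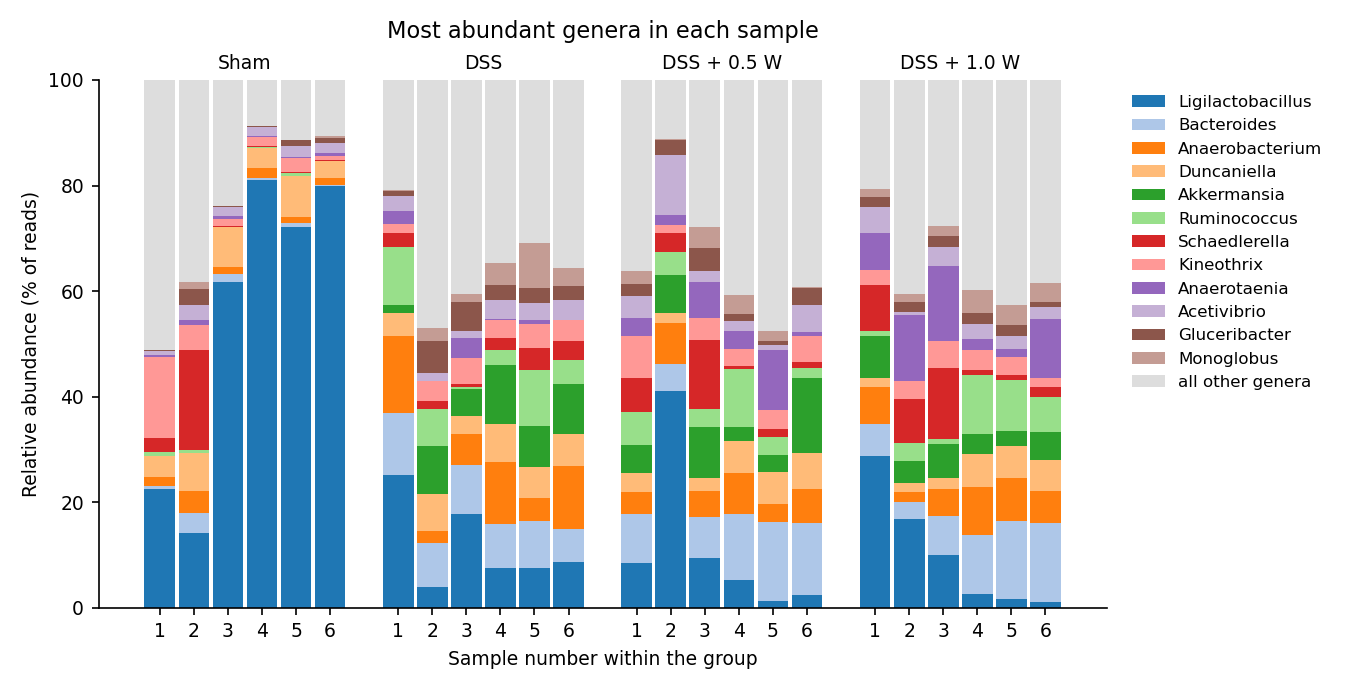
Relative abundance of the 12 most abundant genera in each of the 24 samples, as stacked bars in percent of reads, with all other genera in grey. Ligilactobacillus averages 55.2% of reads in Sham and 11.8% in DSS.

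The comparison of DSS with Sham asks which bacteria differ when colitis is induced. Akkermansia, which feeds on intestinal mucus, was absent from the reads of all 6 Sham samples and made up 7.33% ± 3.52 (SD, n = 6) in DSS, at least 2029-fold higher when 3 reads over all Sham libraries are allowed (adjusted p 2.21e-10). Bacteroides, which degrades plant and mucus polysaccharides, rose from 1.24% to 8.81% (log2 fold change 2.36, adjusted p 0.00129), and all 6 DSS samples lay above every Sham sample. Ruminococcus rose from 0.370% ± 0.269 to 6.12% ± 4.22 (SD, n = 6 each; log2 fold change 3.57, adjusted p 0.00129). Ligilactobacillus fell by 3.21 on the log2 scale (adjusted p 0.0151), and all 6 DSS samples lay below the Sham mean. Sham samples 1 and 2, at 22.4% and 14.2%, lay below DSS sample 1 at 25.1%, and Sham sample 2 below DSS sample 3 at 17.9% as well, while Sham samples 3 to 6 held 61.7% to 81.0%. The call ended by exact permutation of percentages (Benjamini-Hochberg 0.0619 over genera).

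Anaerobacterium rose from 1.90% ± 1.15 to 8.44% ± 4.96 (SD, n = 6 each; log2 fold change 1.52, adjusted p 0.0424). Monoglobus, a pectin degrader, rose from 0.326% ± 0.550 to 3.41% ± 2.83, Lawsonibacter from 0.0800% ± 0.124 to 2.09% ± 1.13, and Parabacteroides from 0.283% ± 0.217 to 1.78% ± 0.647 (SD, n = 6 each). Anaerostipes, a butyrate producer, rose from 0.0135% ± 0.0282 to 1.69% ± 1.68, and Turicibacter from 0.00890% ± 0.0139 to 0.796% ± 0.472 (SD, n = 6 each). Romboutsia had 0 reads in Sham and 1.1% ± 1.07 (SD, n = 6) in DSS, at least 305-fold higher (192-fold without DSS sample 3), and Anaerovorax had 0 reads in Sham and was at least 14.4-fold higher. Lachnoclostridium fell from 2.11% ± 3.00 to 0.107% ± 0.118 and Lacrimispora from 1.59% ± 1.84 to 0.0351% ± 0.0408 (SD, n = 6 each). Hungatella had 0 reads in DSS and was at least 103-fold lower than in Sham (42.2-fold without Sham sample 1), where it was seen in 4 of 6 samples. The adjusted p of the genera in these sentences from Monoglobus to Hungatella ran from 6.34e-05 to 0.0207, and at least 5 of 6 DSS samples lay past the Sham mean for each of the genera that rose. Shigella, a genus of Enterobacteriaceae, was called at 1.95% ± 4.74 (SD, n = 6) in DSS against 0 reads in Sham, at least 491-fold higher, but it was seen in 2 of 6 DSS samples, and without DSS sample 3 the bound fell to 2.61-fold and the call ended (adjusted p 0.153). The call of Anaerobacterium ended without Sham sample 1, 2 or 3 or DSS sample 1, 4 or 6 (log2 fold change 1.20 to 1.80 over single samples left out), and that of Parabacteroides without Sham sample 2 (1.61 against 1.77).

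**Figure D2:**
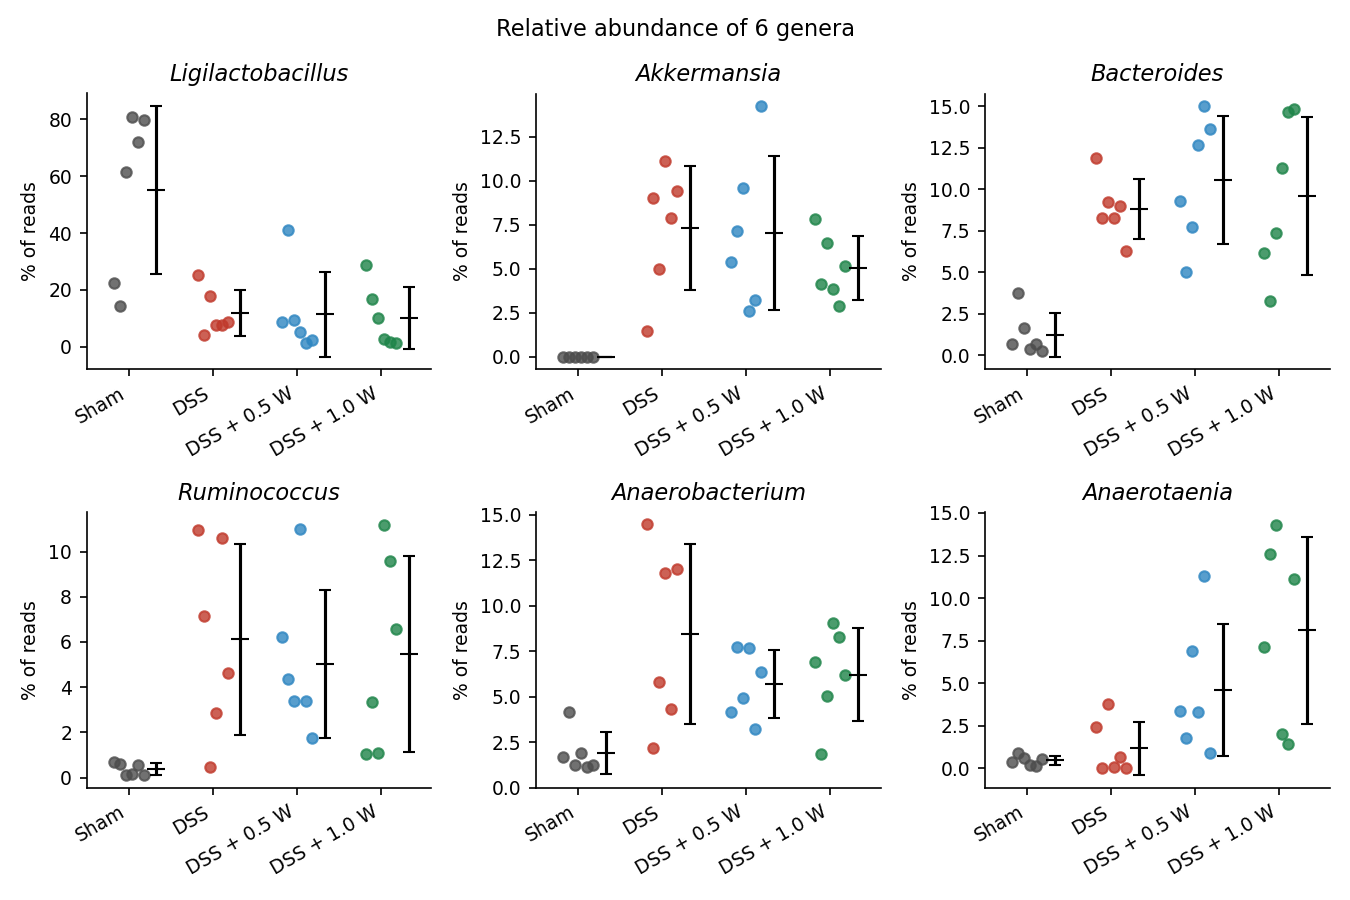
Relative abundance in percent of reads of 6 genera in the 6 samples of each group, with the mean and SD beside the points. Akkermansia is at 0 in all 6 Sham samples and averages 7.33% in DSS.

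In all, edgeR called 29 of 94 genera, 19 higher and 10 lower in DSS, 33 of 129 species (22 higher) and 76 of 326 ASVs (60 higher). DESeq2 called 29 genera, limma on centred log-ratios 23 and exact permutation 13. With library totals in place of TMM factors the genera called were again 29, of which 22 were higher, and the median log2 change over genera moved from 0.0064 to 0.73. Of the 16 genera named above, Akkermansia, Bacteroides and Lacrimispora were called under all 11 other settings tried. By exact permutation of percentages, the calls of Ligilactobacillus, Ruminococcus, Lawsonibacter, Anaerostipes, Turicibacter, Romboutsia, Anaerovorax, Hungatella and Shigella ended (Benjamini-Hochberg 0.0543 to 0.622). With the sample number as a block those of Monoglobus, Lawsonibacter, Anaerostipes, Shigella and Anaerobacterium ended (adjusted p 0.0557 to 0.0994). Their log2 fold changes were then 2.90, 3.86, 5.84, 8.26 and 1.44, against 2.87, 4.43, 6.32, 10.8 and 1.52 in the main fit. With limma the calls of Lawsonibacter, Anaerobacterium and Shigella ended (adjusted p 0.105 to 0.512), at log2 fold changes of 3.64, 1.18 and 1.53. Anaerobacterium also lost its call with only DSS and Sham in the fit (adjusted p 0.0658), and DESeq2 gave Shigella no adjusted p. Without Sham samples 1 and 2, left out after the data were seen because they lay apart from the other Sham samples, edgeR called 17 genera, and Anaerobacterium, Lachnoclostridium, Parabacteroides and Anaerovorax were not among them. Log2 fold changes of these genera were then 1.47, -3.27, 1.46 and 5.93, against 1.52, -4.69, 1.77 and 5.90 with all samples. The ASV count was 31 without Sham sample 1, 29 without Sham sample 4, 44 without Sham sample 6, 40 without DSS sample 2 and 49 without DSS sample 5.

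The 8 named species were Ligilactobacillus murinus, which fell by 3.25 on the log2 scale, and Anaerobacterium chartisolvens, Bacteroides caccae, Akkermansia muciniphila, Monoglobus pectinilyticus, Ruminococcus callidus, Lawsonibacter asaccharolyticus and Parabacteroides goldsteinii, which rose. Ruminococcus callidus was at 3.16% ± 4.70 in DSS and 0.0426% ± 0.104 in Sham (SD, n = 6 each), and was seen in 3 of 6 DSS samples.

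By phylum, Bacteroidota rose from 8.24% ± 3.80 to 17.3% ± 1.76, Firmicutes fell from 89.9% ± 4.73 to 71.7% ± 5.08, and Verrucomicrobia rose from 0 reads to 7.33% ± 3.52 (SD, n = 6 each; exact p 0.0021645 each, the smallest possible, Benjamini-Hochberg 0.00505 over 7 phyla). All 6 DSS samples lay beyond every Sham sample for each of these phyla. The log2 Firmicutes to Bacteroidota ratio was 3.59 ± 0.79 in Sham and 2.05 ± 0.17 in DSS (SD, n = 6 each; exact p 0.0021645, the smallest possible, Benjamini-Hochberg 0.00866 over 4 comparisons), a 2.90-fold lower ratio in DSS. These are shares of one total, and Ligilactobacillus belongs to Firmicutes. Its fall alone raises the share of Bacteroidota and lowers the ratio. Bacteroidota were not compared outside the Ligilactobacillus reads, so a change of that phylum relative to the remaining bacteria is not shown. Families that rose were Akkermansiaceae, Bacteroidaceae, Tannerellaceae, Oscillospiraceae (7.72% ± 4.54 to 27.6% ± 8.18), Peptostreptococcaceae and Turicibacteraceae, and Lactobacillaceae fell from 56.6% ± 28.8 to 12.0% ± 7.95 (SD, n = 6 each; exact permutation, Benjamini-Hochberg 0.0159 to 0.0476 over 22 families). Of these 7 families, 4 passed without DSS sample 2, 3, 4, 5 or 6. The calls of Lactobacillaceae, Peptostreptococcaceae and Turicibacteraceae ended each time (exact permutation, Benjamini-Hochberg 0.0556 to 0.0816).

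Among the fixed lists, the mucus-associated list rose from 0.360% ± 0.619 (0.111% without Sham sample 2) to 7.68% ± 3.62, where 1 of 3 tested genera rose, Akkermansia, and Mucispirillum was at 0.350% in DSS and 0.339% in Sham (SD, n = 6 each; exact p 0.00433, Benjamini-Hochberg 0.0173 over 12 lists). The Bacteroides group rose from 1.54% ± 1.39 to 10.6% ± 1.51 with both tested genera up, and Oscillospirales rose with 6 genera up and 1 down of 26 (exact permutation, Benjamini-Hochberg 0.0173 each). Erysipelotrichia rose from 1.42% ± 0.717 to 3.51% ± 1.33, where Turicibacter was the genus of 5 that rose, and the list of lactobacilli and bifidobacteria, which held no Bifidobacterium, fell from 56.6% to 12.0% with both of its genera down, Ligilactobacillus and Lactobacillus (1.38% ± 1.42 in Sham, 0.190% ± 0.171 in DSS; SD, n = 6 each) (exact permutation, Benjamini-Hochberg 0.0260 each). Butyrate producers were at 7.35% ± 7.54 in Sham and 10.3% ± 2.44 in DSS (SD, n = 6 each; exact p 0.396), the list passed without Sham sample 1, where Sham averaged 4.42% (exact permutation, Benjamini-Hochberg 0.0260), and 3 of their 11 genera rose, Anaerostipes, Coprococcus and Lawsonibacter. Facultative anaerobes were at 0.0141% ± 0.0183 and 2.56% ± 6.02 (exact p 0.0628, n = 6 each). Sham averaged 0.00857% without Sham sample 5 and DSS 0.104% without DSS sample 3, and the list passed without DSS sample 1 or 5 (exact permutation, Benjamini-Hochberg 0.0260 and 0.0468). Both tested genera, Shigella and Enterobacter, were called, each seen in 2 DSS samples. Lachnospiraceae were at 19.3% ± 19.8 and 21.6% ± 3.19 (exact p 0.749, n = 6 each), with 3 genera up and 5 down of 29, and Clostridiaceae with Peptostreptococcaceae at 1.98% ± 1.84 and 3.59% ± 2.0 (exact p 0.173, n = 6 each), with 1 up and 1 down of 4. Muribaculaceae were at 6.72% ± 2.75 and 6.54% ± 2.11 (exact p 0.926, n = 6 each), the list of Rikenellaceae and Prevotellaceae, here 1 ASV named Prevotella, at 0 reads and 0.204% ± 0.501, all in DSS sample 2 (exact p 1, n = 6 each), and bacteria foreign to the gut at 0 reads and 0.0349% ± 0.0450, or 0.0194% without DSS sample 2 (exact p 0.182, n = 6 each). The counts of genera up and down in each list were the same when adjusted over the list alone. Lists and families are also shares of one total, and the fall of Ligilactobacillus alone raises the shares of the others. They were not compared outside its reads, so whether each rose relative to the remaining bacteria was not tested. Of the 5 lists that passed, 3 passed without DSS sample 2, 4 or 6. The list of lactobacilli and bifidobacteria lost its call without DSS sample 2, 4, 5 or 6, and Erysipelotrichia without DSS sample 2, 4 or 6 (exact permutation, Benjamini-Hochberg 0.0519 to 0.0623).

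The composition of DSS and Sham samples differed, with 40.8% of the variance of Bray-Curtis distances between the groups (exact permutation p 0.0021645, the smallest possible, Benjamini-Hochberg 0.00577 over 8 comparisons). Distances to the group centroid did not differ measurably (0.340 ± 0.0839 in DSS, 0.338 ± 0.137 in Sham; SD, n = 6 each; exact p 0.978). Shannon diversity was 4.4 ± 0.290 in DSS and 3.85 ± 0.882 in Sham (SD, n = 6 each; exact p 0.184, Benjamini-Hochberg 0.554 over 14 comparisons), and observed ASVs were 305 ± 70.6 and 253 ± 83.6 (exact p 0.260, n = 6 each). Shannon diversity passed unadjusted at genus level, where the difference was 1.21 (exact p 0.0195, n = 6 each), and without Sham sample 1, where it was 0.803 (exact p 0.0390).

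**Figure D3:**
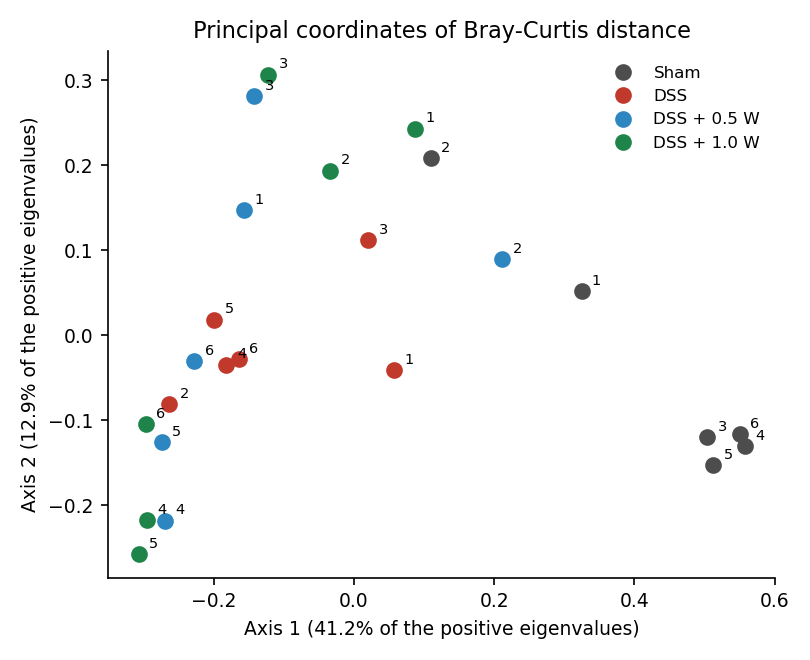
Principal coordinates of Bray-Curtis distances of the 24 samples, numbered within their group. The axes hold 41.2% and 12.9% of the positive eigenvalues, and Sham samples 3 to 6 lie at 0.504 or above on the first axis, where all other samples lie at 0.325 or below.

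The comparison of DSS with LIPUS at 0.5 W against DSS alone asks whether ultrasound changes the bacteria of mice with colitis. Akkermansia was at 7.03% ± 4.37 of reads with 0.5 W and 7.33% ± 3.52 without, and Bacteroides at 10.6% ± 3.85 and 8.81% ± 1.83 (SD, n = 6 each). The 5 genera with the smallest p were Kurthia (0.346% ± 0.568 against 0.00249% ± 0.00610, seen in 2 of 6 LIPUS samples), Anaerocolumna (0.0414% ± 0.0679 against 0 reads), Bittarella (0.00228% ± 0.00559 against 0.0386% ± 0.0184), Sinanaerobacter (0 reads against 0.0133% ± 0.0162) and Ruthenibacterium (0 reads against 0.0134% ± 0.0165; SD, n = 6 each). Their adjusted p ran from 0.285 to 0.423. With edgeR 0 of 94 genera passed, and 7 had an unadjusted p under 0.05. In simulated data with changes seeded at 0.5 W alone, the unchanged comparison of 1.0 W with DSS gave such a p at rates that amount to 6.17 of 94 genera, 9.91 of 129 species and 43.2 of 326 ASVs. DESeq2 called 0 and exact permutation 0, and limma on centred log-ratios called 1, Bittarella. With edgeR 0 of 129 species and 0 of 326 ASVs passed (9 and 32 at an unadjusted p under 0.05), and DESeq2 called 0 species and 2 ASVs.

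In the 1.0 W group, Anaerotaenia, a genus of Lachnospiraceae, was at 8.11% ± 5.48 of reads against 1.17% ± 1.58 in DSS (SD, n = 6 each; log2 fold change 2.60, adjusted p 0.292), above the DSS mean in 6 of 6 samples, and the difference did not pass. Kurthia (0.534% ± 0.633 against 0.00249% ± 0.00610, seen in 3 of 6 LIPUS samples), Anaerocolumna (0.0555% ± 0.0651 against 0 reads), Hungatella (0.0410% ± 0.0645 against 0 reads) and Marinilactibacillus (0.0339% ± 0.0412 against 0.00157% ± 0.00384) were the other genera of smallest p (SD, n = 6 each; adjusted p 0.208 to 0.600). Akkermansia was at 5.05% ± 1.83 and Ruminococcus at 5.48% ± 4.35 (SD, n = 6 each). With edgeR 0 of 94 genera passed, and 5 had an unadjusted p under 0.05. DESeq2, limma and exact permutation called 0 genera each, with the same limit on exact permutation as at 0.5 W. With edgeR 0 of 129 species and 0 of 326 ASVs passed (11 and 43 at an unadjusted p under 0.05), and DESeq2 called 0 species and 2 ASVs. In the simulated data with 1.0 W unchanged from DSS, such a p arose at rates that amount to 6.17 genera, 9.91 species and 43.2 ASVs. Hungatella passed when adjusted over the list alone, 1 of the 4 tested genera of Clostridiaceae with Peptostreptococcaceae, and it was seen in 2 of 6 LIPUS samples.

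With both LIPUS groups set against DSS, Anaerotaenia was at 6.35% ± 4.88 (SD, n = 12) against 1.17% ± 1.58 (SD, n = 6) and above the DSS mean in 11 of 12 samples (adjusted p 0.381). Kurthia, Anaerocolumna, Hungatella and Bittarella were the other genera of smallest p, with adjusted p from 0.222 to 0.381. In both doses together, Kurthia and Anaerocolumna were each seen in 5 of 6 samples numbered 4 to 6 within their group and in 0 of 6 numbered 1 to 3, a division of the LIPUS samples noticed after the data were seen that also parted them by distance. With this division as a block, edgeR called 0 genera at 0.5 W, at 1.0 W and in both together (6, 3 and 6 at an unadjusted p under 0.05). With edgeR 0 of 94 genera passed, and 10 had an unadjusted p under 0.05. DESeq2 and exact permutation called 0, and limma on centred log-ratios called 2, Anaerotaenia and Bittarella. The mean of library totals was 12438 reads in the LIPUS groups and 19533 in DSS (exact p 0.00458, Benjamini-Hochberg 0.0321 over 7 comparisons).

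By exact permutation, 0 of 7 phyla, 0 of 22 families and 0 of 12 fixed lists passed at 0.5 W, at 1.0 W and in the pooled comparison. At an unadjusted p under 0.05 there were 0 phyla and 0 lists in each, and 1, 2 and 1 families. Without DSS sample 1, 1 family passed in the pooled comparison, Eubacteriales Family XIII, at 0.0968% ± 0.0501 with LIPUS and 0.231% ± 0.0520 in DSS (SD, n = 12 and 5; exact p 0.000162, Benjamini-Hochberg 0.00356 over 22 families). The list of smallest p at 1.0 W was Lachnospiraceae, at 30.2% ± 10.4 against 21.6% ± 3.19 in DSS (SD, n = 6 each; exact p 0.0736, Benjamini-Hochberg 0.883 over 12 lists). The log2 Firmicutes to Bacteroidota ratio was 2.07 ± 0.78 at 0.5 W and 2.41 ± 0.91 at 1.0 W against 2.05 ± 0.17 in DSS (SD, n = 6 each; exact p 0.965 and 0.387). Shannon diversity was 4.29 ± 0.301 at 0.5 W and 4.28 ± 0.240 at 1.0 W against 4.4 ± 0.290 in DSS (SD, n = 6 each; exact p 0.530 and 0.450). Observed ASVs were 261 ± 58.5 and 256 ± 34.6 against 305 ± 70.6 (SD, n = 6 each; exact p 0.277 and 0.152). Without DSS sample 1 the differences passed unadjusted for the 1.0 W group (-74.3, exact p 0.0108) and both LIPUS groups (-71.4, exact p 0.00953). That sample had the smallest library (11144 reads) and the fewest observed ASVs (182) of DSS. Library totals averaged 12438 reads with LIPUS and 19533 in DSS. ASVs were compared at a common depth, but whether the library totals still moved these differences was not tested.

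**Figure D4:**
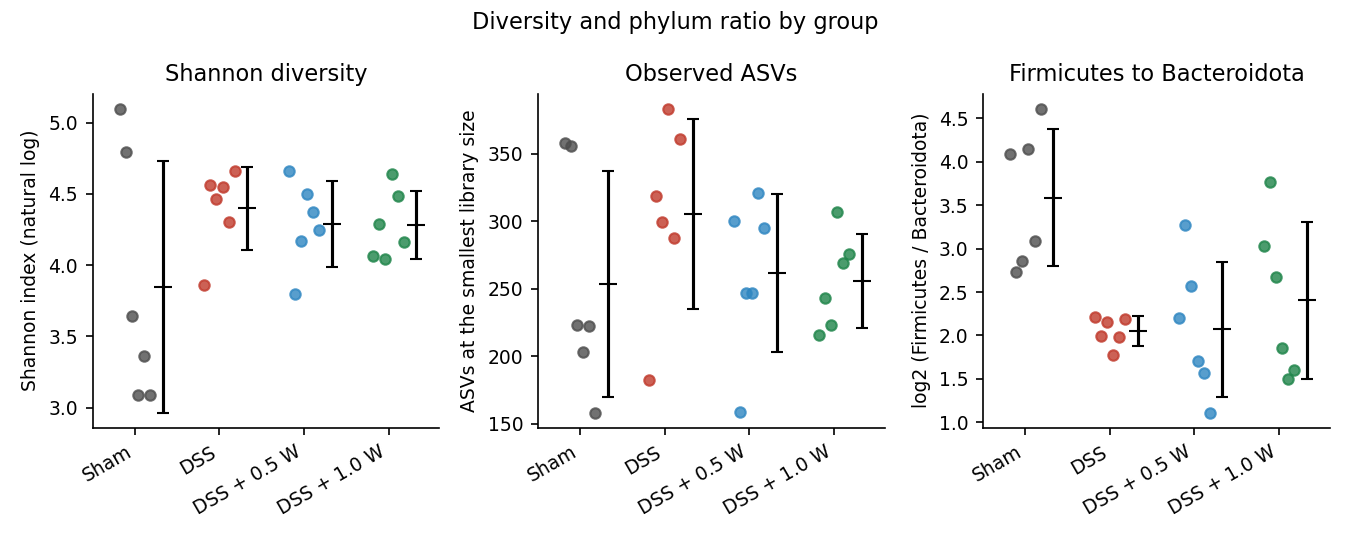
Shannon index, observed ASVs at the smallest library total and log2 Firmicutes to Bacteroidota ratio in the 6 samples of each group, with the mean and SD beside the points. The ratio averages 3.59 in Sham and 2.05 in DSS.

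Of the variance of Bray-Curtis distances, 10.1% lay between 0.5 W and DSS (exact permutation p 0.338) and 14.6% between 1.0 W and DSS (exact p 0.0909). For both LIPUS groups against DSS it was 9.88% (exact p 0.0747, Benjamini-Hochberg 0.120 over 8 comparisons). Random labels also give shares above 0, so shares that did not pass are not read as an effect of LIPUS. The pooled comparison passed unadjusted with Aitchison distance (exact p 0.0166), with Jaccard distance (exact p 0.0307) and without sample 2 of the 0.5 W group (exact p 0.0428). Library totals were lower with LIPUS (mean 12438 reads) than in DSS (19533), and whether depth moved the Aitchison result was not tested. All of these permutations run freely across the sample numbers. With labels permuted within numbers 1 to 3 and 4 to 6, a choice made after the data were seen, the exact p was 0.21 at 0.5 W, 0.025 at 1.0 W and 0.0108 for both together (Benjamini-Hochberg 0.28, 0.05 and 0.0431 over 4 comparisons). The labels do not say whether DSS and LIPUS samples of one number belong together, so this pass rests on an unverified division. The number set had an R2 of 0.268 within DSS (exact permutation p 0.2) and 0.406 within Sham (exact permutation p 0.1). The 10 splits allow no exact p under 0.1, and DSS did not reach that limit. The mean Bray-Curtis distance to the Sham samples was 0.769 ± 0.0689 in DSS, 0.775 ± 0.105 at 0.5 W and 0.786 ± 0.0930 at 1.0 W (SD, n = 6 each; exact p 0.907 and 0.734).

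Between the doses, Anaerotaenia was at 8.11% ± 5.48 at 1.0 W and 4.6% ± 3.87 at 0.5 W, and Acetivibrio at 2.79% ± 1.43 and 4.33% ± 3.83 (SD, n = 6 each). With edgeR 0 of 94 genera passed, and 3 had an unadjusted p under 0.05, while DESeq2, limma and exact permutation called 0. Exact permutation had the same limit here as for each dose against DSS. Of the variance of Bray-Curtis distances, 4.90% lay between the doses, which did not pass (exact permutation p 0.816, and 0.6 within numbers 1 to 3 and 4 to 6).

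Against Sham, both LIPUS groups held Akkermansia (at least 1946-fold higher at 0.5 W and at least 1394-fold at 1.0 W) and more Bacteroides and Ruminococcus (log2 fold changes 2.45 and 3.18 at 0.5 W, 2.35 and 3.19 at 1.0 W), while Ligilactobacillus fell by 2.80 and 3.59 on the log2 scale. Duncaniella fell by 1.30 and 1.43 on the log2 scale, and both calls ended with library totals, where the log2 fold changes were -0.317 and -0.509 (adjusted p 0.710 and 0.460), with no filter and by exact permutation of percentages. At 1.0 W the call also ended with only the compared groups in the fit (adjusted p 0.0653). At 0.5 W it also ended with TMMwsp factors (adjusted p 0.0642), with the sample number as a block (adjusted p 0.0636), and without Sham sample 3 or 5 or sample 1, 3 or 5 of the 0.5 W group (log2 fold changes from -1.73 to -1.03). Anaerotaenia rose by 3.33 on the log2 scale at 1.0 W, a call that ended with limma and without Sham samples 1 and 2. EdgeR called 23 genera at 0.5 W, 14 higher and 9 lower, and 31 at 1.0 W, 21 higher and 10 lower. With library totals these were 29 (24 higher) and 30 (26 higher), with DESeq2 30 and 36, with limma 24 and 26 (12 higher at 1.0 W) and with exact permutation 15 and 21. Without Sham samples 1 and 2 they were 13 and 12. The 1.0 W count was 19, 18, 20 and 19 without Sham samples 1, 3, 4 and 5 and 19 without sample 4 of the 1.0 W group. The Ligilactobacillus call at 0.5 W ended without Sham sample 4, 5 or 6 or without sample 1, 3, 5 or 6 of the 0.5 W group, with log2 fold changes from -4.67 to -2.55 over single samples left out. It also ended with sample 6 of the 0.5 W group moved to 1.0 W. By exact permutation of percentages it ended at both doses (Benjamini-Hochberg 0.0775 at 0.5 W and 0.0531 at 1.0 W).

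Of the 19 genera that rose in DSS, 12 also rose at 0.5 W and 17 at 1.0 W, and of the 10 that fell, 7 fell in each LIPUS group, with 0 in opposite directions. These comparisons share the Sham samples, which alone makes calls overlap. Unrelated calls would share 2.83 genera up and 0.957 down at 0.5 W and 4.24 and 1.06 at 1.0 W. Groups simulated with no change from Sham shared a mean of 0.01, but such groups yield few calls to share. That value therefore does not measure how far the shared Sham samples raise the overlap. The groups also differed from Sham in Bray-Curtis distances, with 40.6% of the variance at 0.5 W (exact permutation p 0.00433, Benjamini-Hochberg 0.00866) and 43.4% at 1.0 W (exact permutation p 0.0021645, the smallest possible), and the 4 groups together held 38.4% (permutation p 0.0001). With separate Sham samples in each comparison, means of 4.55 genera (0.5 W) and 5.05 (1.0 W) rose in both, and 1.80 and 1.70 fell in both. With the Sham samples divided in this way the means called were 8 genera up and 5.9 down for DSS, 6.95 up and 4.2 down at 0.5 W, and 7.65 up and 4 down at 1.0 W. Unrelated calls of these numbers would share 0.576 up and 0.235 down at 0.5 W and 0.644 and 0.234 at 1.0 W. Whether genera moved back toward Sham with LIPUS was measured across 94 genera. With separate DSS samples, the correlation of the DSS change with the change of both LIPUS groups together averaged -0.101 (SD 0.103 over 20 splits), inside the range of -0.230 to 0.191 that held the central 95% of simulated groups with no LIPUS change. It averaged -0.130 at 0.5 W (simulated -0.216 to 0.204) and -0.0657 at 1.0 W (-0.197 to 0.173). With all DSS samples in both contrasts it was -0.400 at 0.5 W, below the simulated range of -0.372 to 0.0228. It was -0.309 at 1.0 W and -0.375 for both together, inside their simulated ranges (-0.375 to -0.0119 and -0.406 to -0.0445).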

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

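A sample was singled out where its gap to the nearest of its group exceeded the critical share of the group's range in Dixon's test at 95%. For independent, normally spread values chance singles out about 1 in 20 groups, 6.95 of the 139 tested, and 24 were found. In 3 of these the other samples all held 0 reads, where any sample with reads is singled out whatever its size, so they are no evidence, and the other 21 stand against 6.8 expected in 136 groups. Many values here are shares close to 0, and several flags count the same reads, so the excess over that number is not read as evidence. The tests of the 3 patterns below, and the bounds for the other splits of the samples, were set down after the results were seen.

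Sham sample 2 stood apart in Deferribacteres (1.61% of reads, 95% Wilson interval 1.39 to 1.86), in the mucus-associated list through the same reads (1.61%, 1.39 to 1.86), in Oscillospirales (16.5%, 15.8 to 17.2), Anaerobacterium (4.16%, 3.80 to 4.55), Schaedlerella (19.0%, 18.3 to 19.8), Gluceribacter (3.06%, 2.75 to 3.39) and Monoglobus (1.41%, 1.21 to 1.65), each above the other Sham samples. Sham sample 1 stood above them in butyrate producers (22.0%, 21.2 to 22.9) and Kineothrix (15.4%, 14.7 to 16.1), and Sham sample 4 held 0.0115% Proteobacteria (0.00315 to 0.0419) where the others held 0 reads, a share that 0 reads at their depth also allow.

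DSS sample 3 held 13.4% Proteobacteria (12.9 to 13.9) and 14.8% facultative anaerobes (14.3 to 15.4), where the other DSS samples held at most 0.251% and 0.248%. DSS sample 2 held 1.23% (1.05 to 1.43) of the list of Rikenellaceae and Prevotellaceae, all of it 1 ASV named Prevotella, where the others held 0 reads.

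Sample 2 of the 0.5 W group had a mean Bray-Curtis distance to Sham of 0.573, below the 0.773 to 0.858 of the others, with 41.1% Ligilactobacillus (40.1 to 42.1) and 41.1% of the list of lactobacilli and bifidobacteria (40.1 to 42.1), which held no Bifidobacterium. Sample 4 of that group held 1.49% Actinobacteria (1.26 to 1.77), 1.12% facultative anaerobes (0.916 to 1.36) and 1.41% bacteria foreign to the gut (1.18 to 1.68), of which Cutibacterium, a skin bacterium, was 1.33%, all above the others. In the 1.0 W group, sample 2 held 2.55% Proteobacteria (2.26 to 2.86) and 3.00% facultative anaerobes (2.69 to 3.34), sample 5 held 0.140% bacteria foreign to the gut (0.0861 to 0.227), sample 1 held 0.0171% of the same Prevotella ASV (0.00469 to 0.0624) and sample 6 held less Gluceribacter than the others (0.845%, 0.714 to 1.00).

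Akkermansia had 0 reads in all 6 Sham samples and 1.46% to 14.3% of reads in the 18 other samples. Too few Sham reads are argued against, since 1215 Akkermansia reads would be expected in the pooled Sham libraries at the lowest of those shares. Crowding by Ligilactobacillus is argued against as well, since 650.2 reads would be expected among the other Sham reads. A cage or colony that differs between Sham and the other mice cannot be told apart from DSS, because the cage of each mouse is not given, and 3 genera (Akkermansia, Romboutsia and Variimorphobacter) were at 0 reads on one side and in at least 5 of 6 samples of each group on the other. The effect of DSS itself stays open and untested against it.

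LIPUS samples numbered 1 to 3 lay apart from those numbered 4 to 6 in both dose groups, a split chosen after the distances were seen, so its p is no independent evidence. Number set accounted for an R2 of 0.420 among the 12 LIPUS samples (exact permutation p 0.0021645, the smallest possible for 462 splits) against 0.0490 for dose, which a cage or batch shared between the doses may explain. A trend with read depth as the whole cause is argued against, since number set added an R2 of 0.381 to a model with log2 read depth (exact permutation p 0.0021645), which alone held 0.118, and so is the Ligilactobacillus share alone, since it was 0.374 without those reads. Of 94 genera, 17 passed between the number sets by exact permutation with Benjamini-Hochberg adjustment, among them Bacteroides (6.47% ± 2.12 in numbers 1 to 3, 13.7% ± 1.48 in 4 to 6) and Schaedlerella (8.93% ± 3.80 and 1.20% ± 0.510; SD, n = 6 each). These genera are part of the distances on which the split was chosen, so their tests are no independent evidence for it. No biological explanation was tested, since the labels do not say what the numbers stand for.

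The 6 most abundant Ligilactobacillus ASVs took like shares of their genus in all 24 samples, from 18.2% ± 1.56 for the first to 13.0% ± 2.22 for the sixth (SD, n = 24). Copies of the 16S gene in one genome would hold fixed ratios. A chi-square per degree of freedom under 2 was set as the bound for this, after the results were seen. The value was 2.44, so the test argues against fixed ratios with counting error alone. It was the second lowest of 40 genera with several ASVs and at least 1000 reads, whose median was 35.5 without Ligilactobacillus. Extra error from PCR was not tested, so copies in one genome are not excluded. Sequencing errors of one sequence are argued against, since the least of the 6 held 66.8% as many reads as the most abundant. No biological explanation other than gene copies was tested.

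The counts called were compared with other splits of the same samples, 100 splits per comparison with the real one included. For DSS against Sham, 1 split of 100, the real one, reached its 29 genera (highest other 10), its 33 species (highest other 10) and its 76 ASVs (highest other 51). The same held for 0.5 W against Sham (23 genera, highest other 3, 1 split) and 1.0 W against Sham (31 genera, highest other 6, 1 split). A rank of 1 in 100 makes a random division of the mice an unlikely source but does not exclude it. The splits treat mice as exchangeable, so they cannot tell treatment from a cage that differs between groups. For LIPUS against DSS and between doses the real counts were 0, which all 100 splits reach by necessity, so this comparison says nothing about chance there. The highest other splits gave 1 genus at 0.5 W, 1 at 1.0 W, 2 in the pooled comparison and 1 between doses, 1 and 5 species and 0 and 2 ASVs at 0.5 W and 1.0 W.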

How the results depend on the processing

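The settings without Sham samples 1 and 2 and with number sets 1 to 3 and 4 to 6 as a block or as bounds for permutation were chosen after seeing the data. Over 45 results, 199 of 227 settings other than leaving out single samples, and 513 of 546 with 1 sample left out, kept the direction and the side of the threshold, or a count within 1.5 times. The others follow, and the cause was not tested. Genera called for DSS against Sham were 16 with the sample number as a block, 13 by exact permutation of percentages and 17 without Sham samples 1 and 2. Same-numbered samples correlated little where Sham or DSS was one of the groups (medians -0.0135 to 0.0713). Between the LIPUS doses the median was 0.270, with 4 of 6 numbers over 0.1 and 1 sample closest to its own number. Genera were 1 at 0.5 W and 2 in the pooled comparison against DSS with limma. Against Sham they were 15 at 0.5 W by exact permutation, and 13 at 0.5 W and 12 at 1.0 W without Sham samples 1 and 2. For DSS against Sham, species were 52 with no filter, where more species are tested, 19 with the block and 18 without Sham samples 1 and 2, and ASVs 19, 41 and 37. ASVs were 2 at each dose against DSS with DESeq2.

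The Shannon difference at genus level was 1.21 for DSS against Sham (exact p 0.0195), and turned to 0.0348 at 1.0 W and 0.0134 in the pooled comparison. The pooled R2 of distances was 0.0968 with Aitchison distance and 0.0856 with Jaccard distance. With labels permuted within number sets the same R2 of 0.146 at 1.0 W (exact p 0.025) and 0.0988 pooled (exact p 0.0108) passed unadjusted. The difference in distance to Sham turned to -7.40 at 0.5 W and -6.59 at 1.0 W with Aitchison distance, and to -0.00627 at 0.5 W with its sample 6 moved to 1.0 W. Bacteroidota were 0.973 percentage points higher at 0.5 W than in DSS, the reverse of the slightly higher log2 ratio of Firmicutes to Bacteroidota. The correlation for return toward Sham was -0.376 over the genera called for DSS, which were chosen on the same DSS samples and have no simulated value beside them, so it is not read as return. It was -0.00238 with centred log-ratios.

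With single samples left out, genera ran from 18 to 29 for 1.0 W against Sham, ASVs for DSS against Sham from 29 to 85, families from 4 to 8 and lists from 3 to 6 for DSS against Sham, and families from 0 to 1 in the pooled comparison. The Shannon difference of DSS and Sham ran from 0.401 to 0.803, that of observed ASVs from -74.3 to -34.1 at 1.0 W and from -71.4 to -31.2 pooled, and the pooled R2 from 0.0848 to 0.116. The difference in distance to Sham ran from -0.0145 to 0.0466 at 0.5 W and from -0.00373 to 0.0470 at 1.0 W, and the log2 ratio difference at 0.5 W from -0.22 to 0.21. Of 1960 ASVs 326 met the filter on samples and reads, and whether depth or differences between mice kept out the rest was not tested.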

Other observations

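Between the number sets of the LIPUS samples, genera other than those named above also differed, in tests chosen after the data were seen. Their reads are part of the distances on which the sets were chosen, so the p-values describe the split and are no independent evidence for it. Duncaniella was at 2.28% ± 0.646 in numbers 1 to 3 and 6.20% ± 0.337 in numbers 4 to 6, Ligilactobacillus at 19.1% ± 13.2 and 2.41% ± 1.5, Lawsonibacter at 0.240% ± 0.242 and 2.24% ± 0.578, and Solibaculum at 0.489% ± 0.214 and 1.97% ± 0.661 (SD, n = 6 each; exact permutation, Benjamini-Hochberg 0.0185 to 0.0254 over 94 genera). Marinilactibacillus was seen in 6 of 6 samples numbered 1 to 3 and 0 of 6 numbered 4 to 6. The mean Bray-Curtis distance between samples of different dose was 0.404 within a number set and 0.604 across sets. A division at the same numbers had an R2 of 0.406 in Sham (exact permutation p 0.1) and 0.268 in DSS (exact permutation p 0.2). The 10 splits allow no p under 0.1, and DSS did not reach that limit.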
